A study of Mus musculus with 4 samples.

How the data were processed

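Gene expression was measured with Affymetrix MOE430 arrays in 3 samples of newborn mouse ureter and in 1 pooled sample of whole newborn mice. Per the labels' protocols, ureters were freed from kidney and bladder and frozen, total RNA was isolated on columns, and every sample went through 2 rounds of amplification before biotin labelling. The ureter samples were not pooled, came from males and carried an SMGA/EGFP transgene; the reference was a pool of both sexes without it.

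The deposited values are intensities on a linear scale, 1 per probe set and array, with no detection calls used here. The submitters' processing notes name GCOS, the array maker's software, without a version. The mean intensity of each array after trimming 2% of probe sets at each end was 1500, so the authors' values had been scaled to a common trimmed mean. How background was subtracted before deposit is not given in the sources used here. Such scaling fixes the mean of the bright probe sets and leaves the middle of the distribution free: median intensities were 154 in ureter replicate 1, 259 in replicate 2, 186.5 in replicate 3 and 332 in the reference.

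Choices stated here as fixed were made before the data were examined. The rule for scaling was to keep the deposited scaling if the arrays' median log2 values lay within 0.5 of one another and otherwise to apply quantile normalization. They spanned 1.11, so the arrays were quantile normalized, and the scaling as deposited became an alternative, chosen after seeing the data. Values were taken as log2(intensity + 12.23), the offset being the 10th percentile of all values. A fold on this scale understates the change of dim probe sets. Of 45101 probe sets, 64 controls were left out, and then the 40% with the lowest mean of the 2 group means, which left 27022.

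Probe sets were named from the platform annotation supplied for the arrays: 34958 carried 1 gene symbol, 932 several and 9160 of the non-control probe sets none. Gene identifiers of 34754 probe sets were found in a RefSeq gene table, which changed 0 symbols and was otherwise used for gene spans. Probe sets with several symbols or none entered the tests and were not named. No genomic positions are given, because the sources used here name no build for the arrays. A gene was represented by its brightest probe set, which gave 13714 genes. Of the 5864 genes with more than 1 tested probe set, 6 had probe sets called in opposite directions. Some members of the fixed gene lists were not analysed here: 414 of 493 were measured.

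Ureters were compared with the reference by limma (version 3.58.1 in R 4.3.3), using lmFit and eBayes with an intensity trend, two-sided, with Benjamini-Hochberg adjustment over all probe sets tested and a threshold of 0.05. The fit has 2 residual degrees of freedom, all from the ureters. Gene lists of cell types, pathways and other organs were fixed beforehand, and the 28 with at least 3 measured genes, other than the sex-linked checks, were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. Each list was also tested with an estimated correlation, and its members were adjusted over the list alone. Its median was ranked among 10000 random lists matched on mean expression. With an estimated correlation, camera's test has only the fit's 2 residual degrees of freedom and so little power. Lists with an estimate below the preset, such as heart (-0.074) and brain (-0.053), lost their calls too. The values with an estimated correlation therefore do not show that correlation between genes removes the calls. Other called lists had estimates far above the preset, such as urothelium (0.572), adipocyte (0.336), smooth muscle (0.269), pericyte (0.237) and hedgehog (0.196). If those estimates hold, camera's p-values at the preset correlation are too small for these lists. Neither form of the test settles their calls. Spread between the ureters was described with standard deviations, correlations across probe sets and counts of probe sets over 2-fold apart.

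Genes named in the text follow a fixed rule. It takes the 12 genes with the largest change in each direction among those past the threshold, moved the same way in all 3 ureters and in the brighter part of the arrays, skipping clone names. It adds up to 4 members of each list with the largest change past the threshold, up to 2 with the smallest change, a short set of smooth muscle, urothelial and sex-linked genes named in any case, and the 5 genes that varied most between ureters. It named 162 genes, of which 101 passed. Any other gene is said to have been chosen after its values were seen.

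Background was judged from 27 probe sets for bacterial transcripts that were not spiked in. Their highest intensity was 57.2, 212, 101.5 and 188 in ureter replicates 1, 2 and 3 and the reference, and 66.7%, 53.8%, 60.2% and 61.2% of probe sets lay above it. Where every array of the dimmer group lay at or below that level, the fold is given as "at least", with the dimmer group placed at the background level. This floor was chosen after seeing the data. The precision of every value is limited by the number of arrays.

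The fit and camera were tested 10 times on simulated log2 values of 27022 probe sets in the design of 3 ureters against 1 reference. Offset, normalization and filter were not part of this test. Values were drawn independently, with variances from the fit's own prior and the same spread in the reference. The false calls below hold only under those assumptions, whereas real lists had estimated correlations of up to 0.70 (kidney). With 3000 probe sets changed, 4.61% of those changed by 1 on the log2 scale were called, 36.0% of those changed by 2, 80.7% by 4 and 94.1% by 6, and 3.97% of calls were false. With 200 changed the shares were 0.20%, 6.2%, 43.8% and 57.2%, and 5.40% of calls were false. With no change at most 1 probe set was called. All 10 shifted gene lists and 0 of 10 unshifted ones were called by camera.

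Alternatives were other offsets (1 and the 50th percentile, 231.64), no filter or 60% left out, the deposited scaling, centring on array medians, eBayes without trend or with robust estimation, each ureter left out in turn, a count of probe sets at least 2-fold apart with no test, and the mean over all probe sets of a gene. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.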

Results

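Transcripts of whole ureters from mice at postnatal day 1 (Theiler stage 27) were measured on 3 arrays, and those of a pool of whole mice of the same age and strain (FVB/N) on 1. The ureter is a tube of urothelium, a lining epithelium, surrounded by fibroblasts and smooth muscle that carries urine from kidney to bladder. The ureters came from males with an SMGA/EGFP transgene, named after the smooth muscle gamma-actin gene Actg2, whereas the pool held both sexes and no transgene, so tissue, transgene, sex and pooling change together. The comparison asks which transcripts are richer or poorer in the ureter than in the newborn body as a whole. Nothing says that the 3 ureter samples came from separate animals, so p-values measure only the spread between these samples, which may be technical. The reference had 1 array and was assumed to vary like the ureters. Ureter values are means of n = 3, and differences are log2 ureter minus reference with the standard error (SE) of the limma fit.

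The sex-linked genes were read first, as a check of the labels. Xist, which silences an X chromosome in female cells, was at least 250.0-fold lower in the ureters than in the reference of both sexes (adjusted p = 0.00523). The Y-linked translation factor gene Eif2s3y was higher by 2.13 ± 0.31 (adjusted p = 0.0201), and Uty, a Y-linked demethylase gene, was at least 4.53-fold higher (adjusted p = 0.0440). Kdm5d differed by 1.22 ± 0.45 and did not pass (adjusted p = 0.165), while all 3 Y-linked genes passed when adjusted over the list alone. These values are from the brightest probe set of each gene. A dimmer probe set of Eif2s3y (-0.52) and a dimmer one of Kdm5d (-0.65) lay in the other direction without passing. Without ureter replicate 3 the adjusted p was 0.113 for Eif2s3y and 0.101 for Uty. Uty also lost its call without replicate 1 (0.0693), without replicate 2 (0.0596) and with the scaling as deposited (0.105).

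Genes of the urothelium were among the transcripts most enriched in the ureter. Snx31, a sorting nexin of urothelial cells, was at least 70.6-fold higher, and the uroplakin genes Upk1b and Upk3a, which encode the plaque proteins of the urothelial surface, were 59.7-fold and 53.9-fold higher. Sptssb, a subunit gene of the enzyme that starts sphingolipid synthesis, was 72.9-fold higher, the claudin gene Cldn8 46.7-fold and Tbx18, a transcription factor of the ureteric mesenchyme, 37.6-fold. Pkhd1 was at least 17.1-fold higher, Atp10b at least 10.02-fold, Psca at least 6.998-fold, Lca5l at least 6.63-fold, Ccdc89 at least 4.80-fold and Rasef at least 3.72-fold. Besides Xist, the 12 transcripts with the lowest log2 differences held 11 genes, most of them known from other organs. All were at background in the ureters, so their order is not measured, and genes outside the 12 can have larger bounds than some of them, as Fabp1 does (at least 362-fold). The 11 were the plasma protein genes Apoa1, Ahsg and Fgb (at least 397-fold, 325.5-fold and 317-fold lower), Lor and Lce1c of the cornified skin (366-fold and 98.6-fold), Apoa4 (287-fold), Ucp1 of brown fat (273-fold), Pnliprp1 (209-fold), the muscle gene Myot (189.7-fold), Dcpp1 (136-fold) and Clca4b (127-fold), each figure being a lower bound.

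In all, 1720 of 27022 probe sets passed limma's adjusted p, 795 higher and 925 lower in the ureters, and 444 genes were higher and 651 lower. The share of calls that were higher was 46.2%, against 34.5% (438 higher, 833 lower) with the scaling as deposited, 50.6% (761 higher, 742 lower) with an offset of 1 and 52.8% (832 higher, 743 lower) with median-centred arrays, so which direction had more calls depends on the processing. The median of all probe sets lay at 0.11 in the quantile-normalized data, at -0.15 as deposited and at 0.61 with median-centred arrays, so small differences stand relative to that shift. Leaving out ureter replicate 3, the calls fell to 262 (42 higher, 220 lower), although all 1714 of the earlier calls that were tested kept their sign. That omission took Ccdc89 to an adjusted p of 0.0819 and Rasef to 0.120, and Rasef also lost its call without replicate 1 (0.0527).

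**Figure D1:**
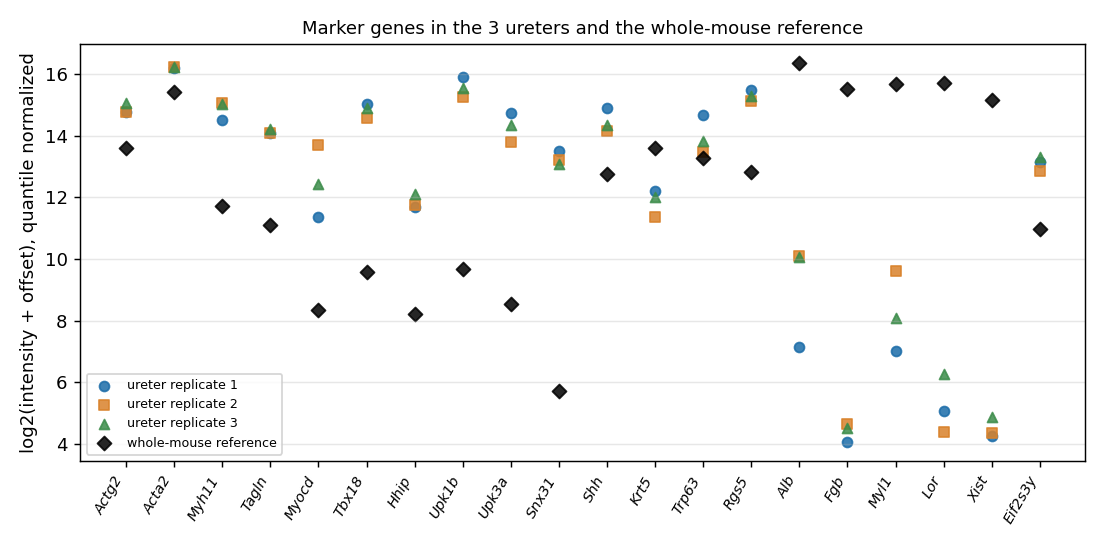
Each point is the level of a gene (horizontal axis) on 1 array, as quantile-normalized log2(intensity + offset) on the vertical axis, with a symbol per ureter replicate and diamonds for the whole-mouse reference. Upk1b lies at 15.57 ± 0.33 (SD, n = 3) in the ureters and 9.67 in the reference, and Alb at 9.11 ± 1.70 against 16.34.

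Many contractile genes of smooth muscle were higher in the ureters. Myh11, the smooth muscle myosin heavy chain gene, was higher by 3.14 ± 0.29 (8.82-fold, adjusted p = 0.00720), Tagln, which encodes an actin-binding protein of smooth muscle, by 3.03 ± 0.24 (8.19-fold), and Synpo2 by 3.63 ± 0.25 (12.4-fold) at its brightest probe set, whereas another of its probe sets was lower (-2.95, adjusted p = 0.0157). Myocd, the coactivator that switches on smooth muscle genes, was higher by 4.14 ± 0.83 (adjusted p = 0.0428), and calponin, Cnn1, by 3.70 ± 0.39. The actin genes Actg2 and Acta2 were higher by 1.25 ± 0.21 (adjusted p = 0.0259) and 0.82 ± 0.13 (adjusted p = 0.0229). The other Acta2 probe sets, both dimmer, gave 3.71 (adjusted p = 0.0210) and 2.30 (adjusted p = 0.0933). Of 29 measured smooth muscle genes, 14 were higher, 2 lower and 13 did not pass, and 19 were higher and 3 lower when adjusted over the list alone. The lower pair were Pln (-3.91 ± 0.79), which encodes a calcium pump regulator of heart and smooth muscle, and Tpm1 (-2.85 ± 0.35), a tropomyosin gene also used by heart and skeletal muscle; Tpm1 was chosen after its value was seen. Its probe sets were called in opposite directions, 1 more lower (-3.41) and 1 higher (1.87, adjusted p = 0.0196), so the direction of Tpm1 is uncertain. The same holds for Tpm2, counted among the higher genes (1.43, adjusted p = 0.0121) although another of its probe sets was called lower (-2.32, adjusted p = 0.0323); Tpm2 was also chosen after its values were seen. Actn1 (0.26) and Cald1 (0.46) did not pass. The list's median difference was 1.39 (camera adjusted p = 1.6e-08), with adjusted p = 0.264 with an estimated correlation. When ureter replicate 3 was left out, 4 members passed in the higher direction, and the adjusted p became 0.129 for Actg2, 0.117 for Acta2, 0.0656 for Cnn1, 0.154 for Myocd and 0.118 for Pln, and Tpm1 did not pass. With the scaling as deposited Acta2 (0.260), Myocd (0.0505) and Pln (0.0719) did not pass, and Synpo2 did not when all its probe sets were averaged (0.36, adjusted p = 0.511).

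Most of the urothelial genes measured were higher than in the whole body. Of 19 measured members 11 were higher and 8 did not pass; adjusted over the list alone, 13 were higher and 1, Krt5, was lower. Shh, the hedgehog ligand that urothelium releases, was higher by 1.69 ± 0.32 (adjusted p = 0.0373) and Upk1a by 2.25 ± 0.43 (adjusted p = 0.0373). Upk2 (0.95 ± 0.42, adjusted p = 0.224), the basal cell regulator Trp63 (0.71 ± 0.46, adjusted p = 0.391), Pparg (0.68) and Elf3 (-0.09) did not pass over all probe sets. Krt5, a keratin gene of basal cells that skin also expresses, differed by -1.74 ± 0.41 and missed the threshold (adjusted p = 0.0615). The list's median was 2.25 (camera adjusted p = 8.5e-10; adjusted p = 0.290 with an estimated correlation). Among 24 genes of epithelia in general, the simple-epithelium keratin genes Krt19 (2.31), Krt18 (2.19) and Krt8 (1.06) and the claudin gene Cldn4 (1.97) were higher, whereas 20 members, Ocln (0.01) and Grhl2 (-0.04) among them, did not pass; over the list alone 5 were higher and 1 lower. That list's median was 0.54 and camera did not call it (adjusted p = 0.0652; adjusted p = 0.680 with an estimated correlation), although it did as deposited (0.0227), with median-centred arrays (0.0232) and without ureter replicate 3 (0.0401). Without replicate 3, 5 urothelial and 1 general epithelial genes were higher, and adjusted p was 0.167 for Upk1a, 0.139 for Shh, 0.0976 for Krt19, 0.0986 for Krt8 and 0.188 for Cldn4. Upk1a and Cldn4 also lost their calls without replicate 1 (0.0658 and 0.0735) and as deposited (0.124 and 0.109), Cldn4 with median-centred arrays (0.0693) and Krt8 as deposited (0.0665). Krt5 passed as lower without replicate 1 (0.0469) and without replicate 2 (0.0433), and 1 general epithelial gene was lower without replicate 1.

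Several transcription factors of the mesenchyme around the ureter were higher. Besides Tbx18 (5.23 ± 0.27), Tbx2 was higher by 2.71 ± 0.51, Gata2 by 2.54 ± 0.29 and Tbx3 by 2.12 ± 0.33. Of 17 such regulators 7 were higher and 10 did not pass, Axin2 (0.04) and Nfia (-0.30) among the latter; over the list alone 8 were higher. The median was 0.75 (camera adjusted p = 0.000146; adjusted p = 0.180 with an estimated correlation). Of 9 hedgehog pathway targets 1 was higher, also over the list alone: Hhip, a hedgehog-binding inhibitor, by 3.63 ± 0.38 (adjusted p = 0.0102). The receptor gene Ptch1 (0.33 ± 0.40, adjusted p = 0.657) and Gli2 (-0.33) did not pass. Camera placed the list just past the threshold (median 0.74, adjusted p = 0.0496; adjusted p = 0.407 with an estimated correlation), and it lost its call without ureter replicate 2 (0.110) or 3 (0.0712) and with median-centred arrays (0.0976). In the retinoid pathway 1 of 14 genes was lower, Rbp4 (-3.81 ± 0.31), the retinol carrier gene of plasma, and over the list alone 2 were lower; Rarg (-0.08) and Rdh10 (-0.03) did not pass. Its median was 0.10 (-0.42 as deposited), its mean -0.38 and camera's direction down, with no call (adjusted p = 0.479; adjusted p = 0.586 with an estimated correlation). Without replicate 3 adjusted p was 0.153 for Tbx2, 0.0768 for Gata2, 0.129 for Tbx3 and 0.0640 for Hhip, and 1 regulator of the mesenchyme passed; Tbx2 also lost its call as deposited (0.0522).

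Some Hox genes, which mark position along the body, were higher, among the posterior members and among the anterior and middle ones. Hoxa10 was higher by 3.43 ± 0.34, Hoxd9 by 2.94 ± 0.48 and Hoxa9 by 1.64 ± 0.33, so 3 of 10 posterior Hox genes passed; over the list alone 5 were higher and 1 lower. Among 14 anterior and middle Hox genes, Hoxb3 (3.02 ± 0.48), Hoxc4 (2.00 ± 0.41) and Hoxb4 (at least 2.17-fold) were higher, and 4 over the list alone. Hoxc9 (0.57), Hoxc10 (0.46), Hoxa5 (0.22) and Hoxb5 (0.42) did not pass. The medians were 1.61 (camera adjusted p = 0.00358; adjusted p = 0.183 with an estimated correlation) and 1.16 (camera adjusted p = 0.00152; adjusted p = 0.180 with an estimated correlation); with members at their bounds the latter was 1.11, and as deposited it was only 0.48. None of the gene calls held without ureter replicate 3, whereas both list calls did; adjusted p was 0.0558 for Hoxa10, 0.0984 for Hoxd9, 0.170 for Hoxa9, 0.113 for Hoxb3 and 0.189 for Hoxc4, and Hoxb4 was not tested. Hoxc4 and Hoxb4 also lost their calls without replicate 1 (0.0603 and 0.0805) or 2 (0.0519 and 0.0627), and Hoxb3 (0.0613) and Hoxc4 (0.131) as deposited, where Hoxb4 was not tested. Hoxc4 did not pass with median-centred arrays either (0.0608).

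Stromal and vascular genes gave a few calls each. The matrix genes Dcn (1.36 ± 0.18), Ogn (1.28 ± 0.22) and Mfap5 (1.10 ± 0.20) were higher among 22 fibroblast and extracellular matrix genes, also over the list alone, while Col5a2 (-0.06) did not pass; the list had a median of 0.13 and no camera call (adjusted p = 0.116; adjusted p = 0.323 with an estimated correlation), but passed with median-centred arrays (0.00706). Of 17 endothelial genes, the receptor gene Tek (2.04 ± 0.32) and Sox17 (1.40 ± 0.27) were higher, also over the list alone, whereas Cdh5 (-0.01) and Sox18 (-0.08) did not pass. The endothelial median was 0.68 (camera adjusted p = 0.0232; adjusted p = 0.264 with an estimated correlation), with no call without ureter replicate 2 (0.0767) or with median-centred arrays (0.0681). Of 6 pericyte genes, Rgs5, a signalling regulator of vessel wall cells, was higher by 2.47 ± 0.21 (adjusted p = 0.00632), also over the list alone, and Cspg4 (-0.21) and Notch3 (0.42) did not pass; the median was 0.90 (camera adjusted p = 0.0291; adjusted p = 0.346 with an estimated correlation), and the call ended without replicate 2 (0.170). Without ureter replicate 3 adjusted p was 0.0973 for Dcn, 0.131 for Ogn, 0.166 for Mfap5, 0.107 for Tek and 0.196 for Sox17. Sox17 also lost its call without replicate 1 (0.0609) and with median-centred arrays (0.0592).

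A minority of the neuronal genes measured passed the threshold as lower. With a list median of -2.27, this does not mean that the others were unchanged. Of 12 genes of peripheral and autonomic neurons 3 were lower, the tubulin gene Tubb3 (at least 22.2-fold), the neurofilament gene Nefl (-4.13 ± 0.45) and Gap43 (-2.67 ± 0.53), and 5 over the list alone; Th (-0.01) and Ret (-0.15) did not pass. The median was -2.27 (camera adjusted p = 0.00100; adjusted p = 0.183 with an estimated correlation). Among 6 Schwann cell genes the myelin gene Mbp was lower by -3.22 ± 0.42, and Sox10 (0.13) and Erbb3 (-0.07) did not pass; over the list alone 1 was higher and 1 lower, the median was -0.12 (0.42 with median-centred arrays) and camera gave adjusted p = 0.581 (adjusted p = 0.709 with an estimated correlation). Of 10 genes of pacemaking and excitability, the chloride channel gene Ano1 (2.65 ± 0.25) and the calcium channel gene Cacna1d (2.39 ± 0.39) were higher and the gap junction gene Gja1 lower (-1.11 ± 0.22), while Kit (-0.49) and Kcnq5 (0.11) did not pass; over the list alone 3 were higher and 2 lower, the median was 0.49 (-0.06 as deposited) and camera gave adjusted p = 0.479 (adjusted p = 0.586 with an estimated correlation). None of these genes passed without ureter replicate 3, with adjusted p of 0.0702 for Tubb3, 0.0501 for Nefl, 0.156 for Gap43, 0.0828 for Mbp, 0.0501 for Ano1, 0.119 for Cacna1d and 0.163 for Gja1. Gap43 (0.0908) and Gja1 (0.403) lost their calls with median-centred arrays, and Cacna1d as deposited (0.0530).

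Most red cell genes measured passed the threshold as lower, and 1 leukocyte gene did. Of 6 erythroid genes 4 were lower, Hemgn (-6.08 ± 0.48), the anion exchanger gene Slc4a1 (-4.25 ± 0.44), Ermap (-3.64 ± 0.63) and the haem synthesis gene Alas2 (-2.56 ± 0.39), and all 6 over the list alone; Klf1 (-3.43 ± 1.19) did not pass over all probe sets. The median was -3.54 (camera adjusted p = 5.9e-06; adjusted p = 0.166 with an estimated correlation). Of 15 macrophage and leukocyte genes 1 was lower, the growth factor receptor gene Csf1r (-1.51 ± 0.26), and 3 over the list alone, while Mrc1 (0.11) and C1qa (-0.17) did not pass; the median was -0.57 (camera adjusted p = 0.0222; adjusted p = 0.329 with an estimated correlation), and the call ended without ureter replicate 3 (0.0746) and with median-centred arrays (0.267). Without replicate 3 adjusted p was 0.0656 for Ermap, 0.113 for Alas2 and 0.132 for Csf1r. Leaving out replicate 2 gave 2 lower macrophage and leukocyte genes. With median-centred arrays Alas2 (0.117) and Csf1r (0.369) did not pass.

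**Figure D2:**
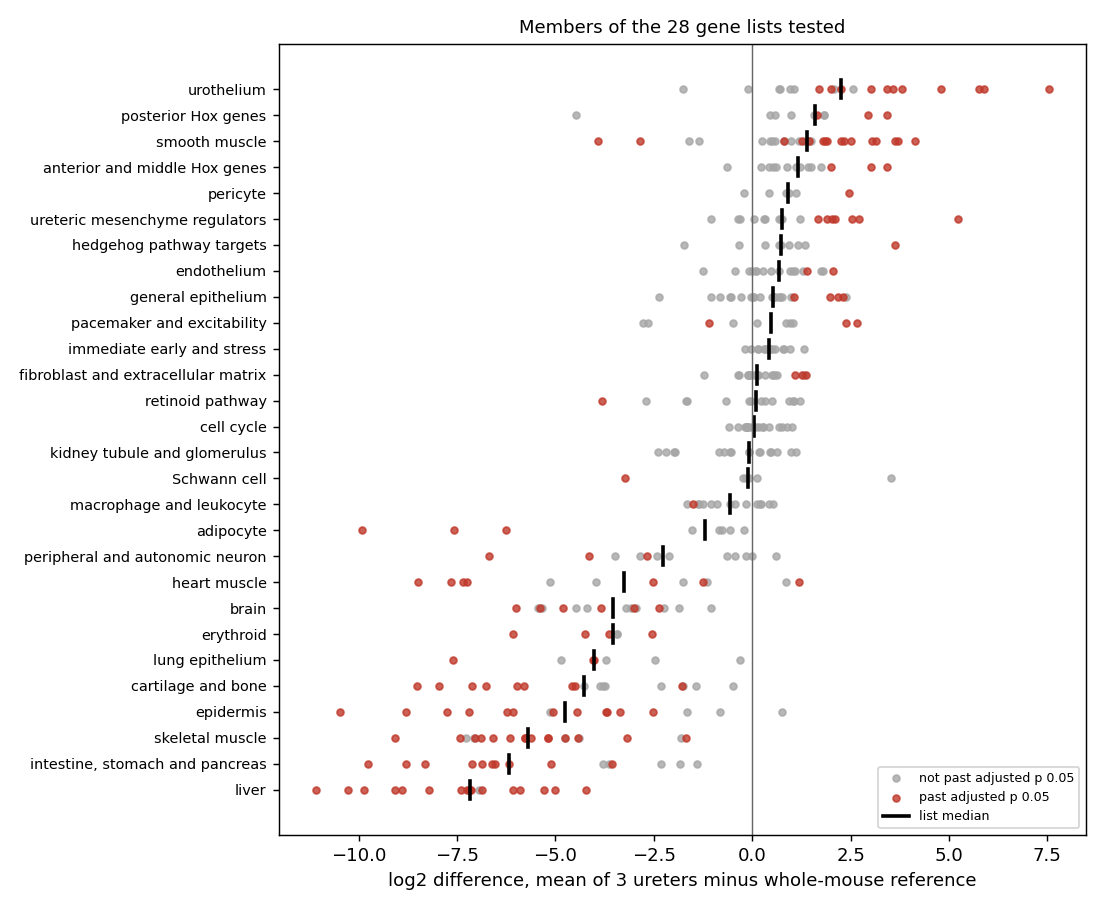
Each point is a measured gene of 1 of the 28 lists tested (vertical axis), placed at its log2 difference between the mean of the 3 ureters and the whole-mouse reference; red points passed adjusted p 0.05, grey ones did not, and black bars are list medians. The medians run from -7.18 for liver to 2.25 for urothelium.

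Many genes typical of other organs were lower in the ureters. Of 18 liver genes 17 were lower, and all 18 over the list alone, with a median of -7.18 (-7.16 with members at their bounds, -6.40 without ureter replicate 1): albumin, Alb, was lower by -7.24 ± 1.17 (adjusted p = 0.0252), Ambp at least 154-fold, and the least moved, Ttr and Apoa2, by -5.01 and -4.23. Of 20 skeletal muscle genes 15 were lower, and 19 over the list alone, among them Myh1 (-9.06 ± 1.07), Myl1 (-7.43 ± 0.94), Mylpf (-7.05 ± 0.55), Neb (-6.89 ± 0.52) and, least, Casq1 (-1.69); Myod1 (-1.81) did not pass. Of 12 heart genes 6 were lower, including Myl3 (at least 60.8-fold), Ttn (-7.65), Myl2 (-7.34) and Csrp3 (-7.25), and 9 over the list alone; 1 was higher, the troponin gene Tnnt2 (1.18 ± 0.23), chosen after its value was seen, and Nkx2-5 (0.86) and Myl7 (-1.16) did not pass. Camera called all 3 lists, with adjusted p of 2.2e-19 for liver (adjusted p = 0.153 with an estimated correlation), 1.6e-17 for skeletal muscle (adjusted p = 0.153 with an estimated correlation; median -5.69, or -5.47 with bounds) and 7.1e-06 for heart (adjusted p = 0.153 with an estimated correlation; median -3.24, or -2.39 with bounds and -4.49 as deposited). Without ureter replicate 3, 11 liver, 8 skeletal muscle and 2 heart genes were lower, and adjusted p was 0.0717 for Alb, 0.0581 for Apoa2, 0.0501 for Myh1, 0.0678 for Myl1, 0.135 for Casq1, 0.1005 for Ttn and 0.0937 for Csrp3. Casq1 also lost its call as deposited (0.0653) and with median-centred arrays (0.409), and Tnnt2 passed neither without replicate 3 nor without replicate 1.

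The genes of skin, skeleton, brain, lung, gut and fat that passed were lower. Of 16 epidermal genes 12 were lower (13 over the list alone), such as Flg (at least 106-fold), Krt1 (at least 87.4-fold) and the desmosome gene Dsg1a (at least 23.0-fold), whereas Casp14 (-0.81) and Ivl (0.75) did not pass; the median was -4.76, or -4.08 with bounds (camera adjusted p = 5.1e-11; adjusted p = 0.153 with an estimated correlation). Of 17 cartilage and bone genes 9 were lower (15 over the list alone), such as Mmp13 (at least 48.5-fold), Cnmd (at least 42.5-fold), Dmp1 (at least 35.1-fold) and Ibsp (-6.75 ± 1.44), and Sp7 (-1.43) and Alpl (-0.47) did not pass; the median was -4.26, or -3.73 with bounds (camera adjusted p = 5.1e-11; adjusted p = 0.153 with an estimated correlation). Of 16 brain genes 6 were lower (15 over the list alone), among them Sox2 (at least 18.02-fold), Slc17a6 (at least 10.98-fold), Mapt (-4.81) and Map2 (-3.84), and Syt1 (-1.87) and Gfap (at least 1.69-fold dimmer) did not pass; the median was -3.52, or -3.08 with bounds (camera adjusted p = 8.3e-11; adjusted p = 0.153 with an estimated correlation). Of 7 lung epithelial genes 3 were lower (5 over the list alone), the surfactant genes Sftpc (-7.60 ± 0.47), Sftpd (-4.05 ± 0.62) and Sftpa1 (at least 8.95-fold), and Sftpb (-2.47) and Abca3 (-0.32) did not pass; the median was -4.01, or -3.22 with bounds (camera adjusted p = 1.8e-05; adjusted p = 0.180 with an estimated correlation). Of 15 genes of intestine, stomach and pancreas 10 were lower (13 over the list alone), among them Fabp1 (at least 362-fold), Clps (at least 34.5-fold) and Fabp2 (-8.30), and Ins2 (-1.84) and Tff1 (-1.40) did not pass; the median was -6.18, or -5.11 with bounds (camera adjusted p = 2.8e-12; adjusted p = 0.153 with an estimated correlation). Of 8 adipocyte genes 3 were lower (4 over the list alone), Ucp1, Adipoq (at least 88.2-fold) and Cidea (-6.25), and Lpl (-0.55) and Slc2a4 (-0.21) did not pass; the median was -1.19 (camera adjusted p = 2.9e-05; adjusted p = 0.264 with an estimated correlation). Without ureter replicate 3 the numbers lower were 6 for epidermis, 4 for cartilage and bone, 3 for brain, 1 for lung, 6 for gut and 3 for fat. Its absence took Dsg1a (0.0783), Dmp1 (0.0641), Ibsp (0.131), Sox2 (0.0706), Slc17a6 (0.113), Sftpd (0.0824) and Sftpa1 (0.108) past 0.05. Without replicate 2, 5 lung genes were lower and Syt1 passed (0.0458).

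Genes of dividing cells and of the early stress response were not called. Of 19 cell cycle genes 0 passed limma's adjusted p over all probe sets or over the list alone, against 1 at an unadjusted p under 0.05; Top2a differed by -0.04 and Cdc20 by 0.05. The median was 0.05 (camera adjusted p = 0.658; adjusted p = 0.838 with an estimated correlation). Of 15 immediate early and stress genes 0 passed limma's adjusted p in either way, against 2 at an unadjusted p under 0.05, with Fosb at 0.14 and Ccn2 at -0.03. The median was 0.43 (camera adjusted p = 0.0705; adjusted p = 0.462 with an estimated correlation), and the list passed with the scaling as deposited (0.0154).

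Of the 28 lists, the kidney genes differed most between the 3 ureters. Their median deviation from the mean of the ureters was -1.23 in replicate 1, 0.75 in replicate 2 and 0.48 in replicate 3. Calb1, a calcium-binding protein gene of the distal tubule, read 8.58, 13.45 and 13.04 in replicates 1, 2 and 3 (SD 2.70), and Defb1, an antimicrobial peptide gene, 9.16, 13.03 and 12.04 (SD 2.01). Gatad2b (8.66, 12.95, 10.24), Arfgef2 (10.48, 13.61, 10.73) and Cux1 (9.81, 12.84, 9.86) were highest in replicate 2. Against the reference, 0 of 17 kidney tubule and glomerulus genes passed limma's adjusted p over all probe sets or over the list alone, against 2 at an unadjusted p under 0.05; Fxyd2 differed by -0.07 and Kap by -0.09. The list's median was -0.09 (camera adjusted p = 0.479; adjusted p = 0.838 with an estimated correlation). Leaving out ureter replicate 1 made it 0.34, with 1 gene higher, Calb1 (2.01, adjusted p = 0.0281), leaving out replicate 2 made it -0.89, and the scaling as deposited -0.78.

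**Figure D3:**
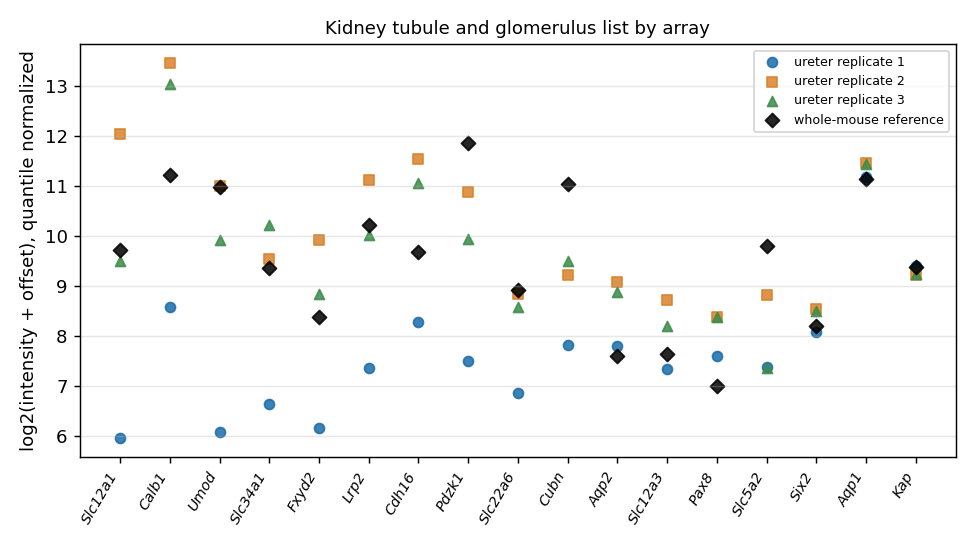
Each point is the level of a kidney tubule or glomerulus gene (horizontal axis) on 1 array, as quantile-normalized log2(intensity + offset) on the vertical axis, with a symbol per ureter replicate and diamonds for the whole-mouse reference. For 15 of the 17 genes both replicate 2 and replicate 3 lie above replicate 1.

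Urothelial genes varied the other way between the ureters, with median deviations of 0.34, -0.31 and -0.14 in replicates 1, 2 and 3, and pericyte genes deviated by -0.37, 0.18 and 0.13. Across 27022 probe sets, which are not independent replicates, the Pearson correlation was 0.900 between replicates 1 and 2, 0.935 between 1 and 3 and 0.929 between 2 and 3, against 0.726, 0.750 and 0.747 with the reference. Over 2-fold differences separated 6165, 3990 and 4716 probe sets in those ureter pairs and 10294, 9464 and 9715 from the reference. The median SD over the ureters was 0.370 on the log2 scale. With each ureter set against the other 2, limma called 0 probe sets each time, against 1940, 2585 and 386 at an unadjusted p under 0.05.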

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

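The level at which control probe sets are listed here (1.5-fold above the reference) and the test of kidney genes among transcripts high in ureter replicate 2 were chosen after the results were seen, while the test of gene span was fixed before.

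Control probe sets for mouse housekeeping transcripts, which enter no comparison, gave intensities at least 1.5-fold above the whole-mouse reference in ureter replicate 2 and in no other ureter among the 19 looked at. The 5' probe set of 18S ribosomal RNA read 1.56-fold the reference (67305 against 43050), and the middle probe set of beta-actin 1.53-fold (1.5295; 58916 against 38521). The 5' probe set of pyruvate carboxylase read 1.53-fold (1.5324; 411.8 against 268.73). The transferrin receptor read 2.45-fold at its 5' probe set (563 against 230) and 2.78-fold at its middle one (335 against 121). The reference's highest unspiked control was 188, above its middle reading and not far below its 5' reading. Both folds, the middle one above all, are therefore limited by background. The 5' to 3' ratio of the transferrin receptor was 0.497 in replicate 2, 0.0261 in replicate 1, 0.399 in replicate 3 and 0.112 in the reference.

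Outside the fixed kidney list and a second described below, 354 genes were at least 2-fold higher in replicate 2 than in both other ureters. Counted over all genes, kidney lists included, replicate 1 had 337 such genes of its own and replicate 3 had 222. Having such genes is thus not particular to replicate 2, and the sources weighed here concern the 354. Reach of the amplification along long genes, or unspliced RNA, may be a source, and across 13714 genes the deviation of replicate 2 had a Spearman rho of 0.0663 with gene span (RefSeq gene table, 99.8% of genes matched), against -0.0303 and -0.0603 for replicates 1 and 3. That value lies between the bounds set in advance, 0.05 and 0.1, so the test does not decide on this source. A weak association with span was present. The median deviation of replicate 2 was -0.144 in the span decile with the shortest genes and -0.0282 in that with the longest. The 354 genes had a median span of 38065.5 bp, against 23601 bp over all matched genes. Gene span is not transcript length, and the deviations of the 3 replicates are not independent of one another. Kidney RNA may be another source. Of the 354 genes 35.6% were at least 1.5-fold higher in replicate 3 than in replicate 1, against 13.7% of all genes. The share again lies between its bounds and leaves the explanation open. Because the 354 were chosen for large differences between arrays, the excess over all genes is no support for kidney RNA. The opposite share, higher in replicate 1 than in replicate 3, was not counted. The labels divide the ureters by nothing, so no biological explanation was tested.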

How the results depend on the processing

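The scaling as deposited, the median-centred arrays for the gene lists, and the background floor were chosen after the data were seen; the other alternatives were fixed before. Among the 101 named genes past the threshold and the called lists, none turned direction (0 reversed values). Named genes without a call lie outside that statement, since differences near 0 can change sign between settings. The balance of calls did turn to more higher than lower with an offset of 1 and with median-centred arrays, as given above. Medians of lists without a call changed sign too, as deposited for pacemaker and retinoid genes (-0.06 and -0.42). They also did so for Schwann cell genes with median-centred arrays (0.42) and for kidney genes without ureter replicate 1 (0.34). Among the 101 named genes past the threshold the calls lost were 52 without ureter replicate 3, 7 without replicate 1, 3 without replicate 2, 31 without the variance trend, 26 without the filter, 12 as deposited, 8 with median-centred arrays, 9 with probe sets averaged, 7 with an offset of 1, 4 with the offset at the 50th percentile and 2 with robust eBayes. Averaging probe sets turned the sign of 3 of all 1095 called genes, with 0 of them past the threshold in the new direction. Against 1720 calls (795 higher, 925 lower), leaving out each ureter gave 262 to 2147 (42 to 965 higher, 220 to 1182 lower), the lowest without replicate 3, which shared 258 calls with the full set. No filter gave 1100 calls (411 higher), eBayes without trend 1074 (335 higher), the scaling as deposited 438 higher, and the offset at the 50th percentile 1809 lower. With no test, 5556 probe sets had all ureters at least 2-fold from the reference (2583 higher, 2973 lower). Without the filter, 13134 probe sets were over 2-fold apart in the ureter pair that differed most, against 6165; more probe sets were compared. Leaving out replicate 3 takes the spread from replicates 1 and 2 alone, on 1 residual degree of freedom. These were the least alike ureters (Pearson correlation 0.900, 6165 probe sets over 2-fold apart). List medians moved little, to 1.27 from 1.39 for smooth muscle and to 2.17 from 2.25 for urothelium. The lost calls therefore do not show that replicate 3 carries the differences. Causes at the other settings were not tested. Camera with an estimated correlation had only the fit's 2 residual degrees of freedom. Its loss of list calls thus does not show that correlation between genes removes them. Nor does it show that calls at the preset hold for lists with estimates far above it, such as urothelium (0.572). Of the lists, 8 were higher and 12 lower with the preset correlation, 0 and 0 with an estimated one (lowest adjusted p = 0.153), 5 to 8 and 11 to 12 when each ureter was left out, and 9 and 12 by rank among random lists. The hedgehog list also failed with the offset at the 50th percentile (0.0637) and with probe sets averaged (0.0911), the endothelial list with probe sets averaged (0.0627) and the pericyte list without the filter (0.0527). No paired analysis was possible because the reference has 1 sample, so the groups share fewer than 2 replicate numbers. Signal over background limits what dim genes can show: 53.8% of probe sets in ureter replicate 2 lay above every unspiked control.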

Other observations

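The tests of gene families, of array scaling and of liver RNA were chosen after the results were seen. The second kidney list was tested as written beforehand. Genes named from that second list, and the liver genes Afp, Apoh, Hp and Cyp2e1, were chosen after their values were seen.

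Gene families were grouped by the stem of their symbols (176 families of at least 10 genes, 352 Fisher's exact tests, adjusted over them), and their members are named after their values were seen. Over all genes 4.75% were lower and 3.24% higher. The tests count genes as independent, whereas genes of a family may move together and all calls share the same reference array. The adjusted p-values of families may therefore be too small. Many keratin genes were lower: 21 of 45 were lower in the ureters (adjusted p = 5.3e-14; 20 as deposited, 11 without ureter replicate 3), among them Krt6b (at least 210.3-fold) and Krt25 (at least 65.5-fold). Another 4, Krt7 (3.81 ± 0.34), Krt19, Krt18 and Krt8, were higher, a number not enriched (adjusted p = 0.802). Of the Lce genes, which encode proteins of the cornified envelope, 11 of 14 were lower (adjusted p = 1.4e-10; 6 without replicate 3). Of cytochrome P450 genes 13 of 53 were lower (adjusted p = 9.4e-05; 5 without replicate 3), with Cyp3a25 at least 46.9-fold, against a higher Cyp7b1 (2.81 ± 0.41), an oxysterol hydroxylase gene. Among clotting factor genes 5 of 14 with this stem were lower (adjusted p = 0.0130; 3 without replicate 3), such as F2 (-6.08) and F10 (-5.66), and among Serpinb genes 5 of 14 (adjusted p = 0.0130; 2 without replicate 3), whereas Serpinb6b was higher (1.71, adjusted p = 0.0486). Myosin heavy chain genes of striated muscle, Myh2 (at least 90.9-fold) and Myh7 (-4.95) among them, made up the 5 of 12 that were lower (adjusted p = 0.00835; 3 without replicate 3), whereas Myh11 and Myh10 (0.85 ± 0.17) were higher.

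Families richer in the ureter were fewer, and nearly every one of their calls was lost without ureter replicate 3. Of integrin alpha genes 4 of 11 were higher (adjusted p = 0.0130), Itga4 (3.15 ± 0.48), Itga1 (2.12 ± 0.39), Itga9 (1.99 ± 0.39) and Itga8 (1.86 ± 0.30); the family's median was 0.56, turned to -0.09 as deposited, and 0 were called without replicate 3. Of genes with the Rgs stem 4 of 15 were higher (adjusted p = 0.0392), Rgs5, Rgs2 (1.70), Rgs16 (at least 3.14-fold) and Rgs9bp (at least 5.98-fold), while Rgs4 (-2.39) and Rgs10 (-1.98) were lower; 1 stayed higher without replicate 3. Zinc finger genes with the Zfp stem were higher in 22 of 278 (adjusted p = 0.00745), as Zfp81 (3.63 ± 0.37) and Zfp287 (3.43 ± 0.53), with 76 higher at an unadjusted p under 0.05; limma called 0 lower (adjusted p = 0.000202), with 2 at an unadjusted p under 0.05. Their median was 0.64, 0.25 as deposited and 0.98 with median-centred arrays, the calls were 7 and 24 in those settings and 0 without replicate 3, and they were dimmer in the reference than genes in general (median 9.19 against 10.61).

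Kidney genes were higher in ureter replicates 2 and 3 than in replicate 1: 15 of 17 (88.2%) were higher in both, with a median shift of 1.84 (3.58-fold). That shift lay at percentile 100 of 10000 random lists matched on level, whose highest median was 0.57. It was thus larger than in genes of like level, but this rank cannot exclude an array effect. The list was taken up because it differed most between the ureters, and the values were already quantile normalized. Its genes also moved together (estimated correlation 0.70), whereas the random lists were drawn gene by gene. Kidney tissue or RNA left on these ureters, which the dissection was meant to remove, is a candidate source: in a second kidney list, 19 of 26 measured genes (73.1%, against 30.3% of all genes) were higher in both replicates, with a median shift of 0.87 (highest random median 0.53), led by Slc17a1 (4.88, 9.66 and 9.66 in replicates 1, 2 and 3) and Hnf4a (5.66, 10.65 and 9.71). Of these lists 13 of 17 and 18 of 26 genes lay above background in replicate 1 too, and 1 gene of the second list, Pvalb, is also in the skeletal muscle list. RNA and amplification controls set replicate 1 apart only in part. In replicates 1, 2 and 3 the 5' to 3' intensity ratio was 0.0261, 0.497 and 0.399 for the transferrin receptor. In the other order it was 0.0601, 0.0462 and 0.0477 for Gapdh. For actin it was 0.205, 0.347 and 0.281, with replicate 3 between the others. Replicate 2 stood apart in the spike-in controls, at 0.593, 1.002 and 0.692 of the reference. It did so too at the 3' probe set of 18S ribosomal RNA (15112, 74754 and 25108). Uneven amplification was not tested as a source of the shift, so the explanation stays open. No biological explanation was tested, since the labels do not divide the ureters.

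Some liver transcripts followed the same order, Alb reading 7.15, 10.10 and 10.08 in ureter replicates 1, 2 and 3. If liver RNA were the whole source, the Alb difference would need 1.14% of the reference's Alb intensity, and the other liver genes should follow at that share, intensity being taken as linear. Over the 12 genes that this would lift above background, the median of observed over needed difference was 0.0642, with 7 under 0.1 and the other 5 between 0.4235 (Hp) and 1.15 (Cyp2e1), which argues against it. Fgb differed by 7.48 intensity units where 527 were needed, whereas Afp (1.01), Cyp2e1 (1.15) and Apoh (0.938) came near their needed difference. What raised those genes stays open, and no biological explanation was tested.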
